A study of Mus musculus with 6 samples.

How the data were processed

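RNA-seq was run on 6 mouse testis libraries, 3 titled Control and 3 titled Middle. Per the labels' protocols, total RNA was extracted with Trizol and made into messenger RNA libraries. Per the submitters' processing notes, reads were trimmed with fastp 0.23.0 and the genome build was GRCm39. The aligner, the counting program and its settings, the strandedness of the kit, the strain and age of the mice and the dose are not given in the sources used here.

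The deposited table held 38715 genes with GRCm39 coordinates, exon lists and a gene length, per the file headers, and RPKM values that the authors had computed for each library. RPKM is a read number scaled to a fixed gene length and a fixed library size, so depth and gene length had already been divided out. Every gene had a value above 0 in at least 1 library. Multiplied by gene length, all values came out as whole multiples of 1 step per library, within a tolerance of 0.001, so the reads behind each value were recovered. The reads summed over genes came to 53456003, 58389391 and 38820385 in Control replicates 1 to 3 and to 47352728, 46649138 and 56435498 in Middle replicates 1 to 3. Even numbers of reads made up 73.3% to 74.7% of the genes with few reads, and 2992 genes held 2 reads in all against 965 with 1, as when both mates of a fragment are counted. For a gene of 1 kb, a single read was worth 0.0171 to 0.0258 RPKM, and the limit that a count of 0 allows, 3 fragments or 6 reads, was 0.103 to 0.155 RPKM. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. The 1 pair of genes with the same coordinates on opposite strands held identical reads, as counting without regard to strand gives, so reads of overlapping or antisense genes are taken as not told apart. How reads that match several places were treated is not given in the sources used here, so near-identical gene copies are reported as uncertain.

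Libraries were grouped by their titles. The design text names a control group and a MES-exposed group, and Middle was read as the exposed group because the titles hold no other group. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries. Counts of reads differed between libraries of 1 group by more than sampling noise for every pair (chi-square per degree of freedom 3.39 to 19.16), so each library counted as 1 replicate.

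The planned test was a test of raw counts, with the test below as its stated substitute for normalized values. The table held RPKM, so the substitute became the main test and the planned count tests were not run. RPKM values were transformed to log2(RPKM + 1), genes with a mean of at least 1 RPKM in at least 1 group were kept (15040 genes, 23675 left out), and limma 3.58.1 (R 4.3.3) with a trend in the prior variance compared Middle with Control, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are on the log2(RPKM + 1) scale and understate the change of low genes. Ratios are ratios of mean RPKM. Before the data were examined, 39 gene lists (testis cell types, neighbouring tissues, pathways and signs of RNA quality) were fixed. The 31 lists with at least 5 tested members were compared with the other genes by camera of limma with a preset correlation of 0.01, two-sided, adjusted over the 31 lists. Camera with an estimated correlation and fry were run as alternatives. The other 8 lists had too few tested members.

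The genes to be named were fixed by a rule before the data were examined. The rule took 10 genes tied to the series title and to steroid synthesis in any case. It took up to 10 genes with the largest rise and 10 with the largest fall that passed the threshold at a mean log2 CPM (reads scaled to a fixed library size) of at least 1, with an established symbol and no overlap of the groups. It also took up to 4 members of each described list with the smallest p. Of the 8 genes past the threshold only mt-Nd3 met the second part, so the other 7 were named after their values were seen. Some genes that the rule or a list takes are not reported here.

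The alternatives were median-of-ratios and upper-quartile scaling, limma-voom on the recovered reads (at least 10 reads in 3 libraries), no filter, a CPM filter (CPM of at least 1 in 3 libraries; planned as a stricter filter, it kept more genes than the main one, 17735), a replicate block, leaving out each library, stricter thresholds, protein-coding genes only, leaving out mitochondrial and the 20 most abundant genes, and pseudocounts of 0.1 and 0.01. Removal of a trend of each library on transcript GC content (loess, span 0.5), limma sample weights, and camera with an estimated correlation with each library left out, were added after seeing the data. Gene types, GC content and transcript sequences came from GENCODE M21 by symbol (34736 genes matched), and none of its coordinates were used. Transcripts were aligned with blastn 2.17.0. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

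The test was tried on simulated data made from the 6 libraries' means and spread, with 200 genes changed. For Middle against Control over 14951 genes it recovered 93.9% of genes changed 4-fold, 90.0% of those changed 2-fold, 55.1% at 1.5-fold and 8.0% at 1.25-fold. Of 136 calls, 14 were unchanged genes. The list test called 0 of 30 lists with no change and all 3 lists with a shift of every member. The simulated genes varied independently of one another, so this trial cannot tell how often lists of correlated genes are called. Their spread followed a smooth curve on gene level, and 136 calls make the adjustment easier than the 8 calls of the real test. The shares recovered can therefore be too high for the real test.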

Results

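The data were gene expression values of whole testis from 6 mouse libraries, 3 from the Control group and 3 from the Middle group, read as the MES-exposed group. The series title concerns exposure in early life, testosterone production, Tgfb1 in mesenchymal cells and the transcription factor GATA2. The libraries held 38820385 to 58389391 reads summed over genes, and 15040 genes were tested. Genes of spermatids, spermatocytes and the somatic cells of the testis were measured in every library.

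**Figure D1:**
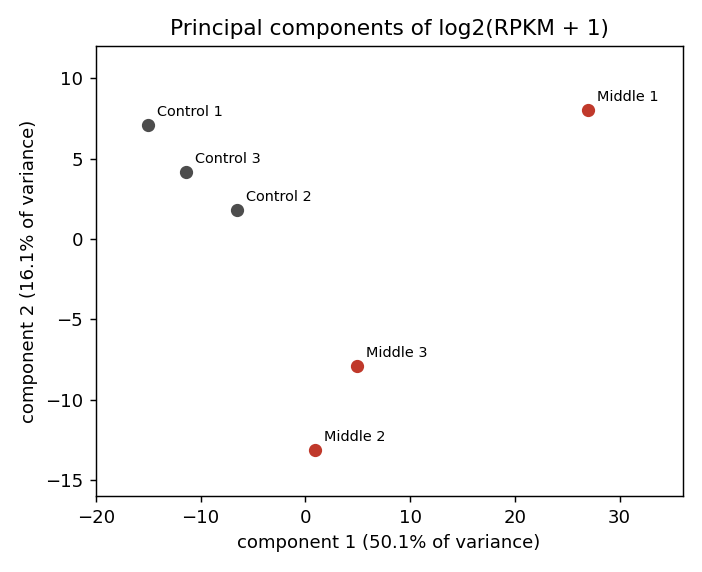
Principal components of log2(RPKM + 1) over the tested genes, with 1 point per library (grey, Control; red, Middle) and the percent of variance on each axis. Component 1 (50.1%) held the Control libraries between -15.0 and -6.48, Middle replicates 2 and 3 at 0.97 and 4.9, and Middle replicate 1 at 27.0.

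Few genes passed the test between Middle and Control testes. The gene test called 8 of 15040 genes, 1 higher and 7 lower in Middle, each with an adjusted p of 0.0267 (limma-trend). An unadjusted p under 0.05 was reached by 3116 genes where chance gives 752, and the libraries of the groups did not overlap for 29.3% of genes where chance gives 10%. The called genes were mitochondrial or non-coding genes or copies in gene clusters, and none of the steroid-producing genes was among them. Mir451a and Mir451b hold the same reads, and mt-Nd3 and Gm28438 are near-identical copies, so the 8 calls are not 8 separate results. The count was 3 without Control replicate 1, 1 without Middle replicate 1 and 0 without any other single library.

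The first question was whether the genes named in the title differed. Tgfb1 (chromosome 7, 25386427 to 25404502), which encodes the cytokine TGF-β1, was at 1.72 ± 0.20 RPKM (SD, n = 3) in Control and 2.23 ± 0.38 (SD, n = 3) in Middle, a ratio of 1.29. Its log2 fold change of 0.24 (SE 0.11) did not pass the test (adjusted p = 0.242, limma), and the libraries of the groups overlapped. Without Middle replicate 1 it was 0.15. Gata2 (chromosome 6, 88170873 to 88184014), a zinc finger transcription factor, was at 5.16 ± 0.69 RPKM in Control and 4.01 ± 0.15 in Middle (SD, n = 3 each). All 3 Middle libraries lay below all 3 Control libraries, with a log2 fold change of -0.29 (SE 0.09) that did not pass the test (adjusted p = 0.181, limma). Whole testis was measured, so the values do not tell which cells held these transcripts.

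Of the 11 GATA factors and cofactors fixed as a list, 8 were tested, and 4 passed when adjusted over the list alone, while 0 passed over all genes. Gata4, the GATA factor of Sertoli and Leydig cells, was at 1.91 ± 0.04 RPKM in Control and 2.46 ± 0.11 in Middle (SD, n = 3 each), and its cofactor Zfpm1 was at 8.56 ± 0.80 and 10.6 ± 0.75 (SD, n = 3 each). The cofactor Ldb1 was at 2.004 ± 0.14 and 2.48 ± 0.11 RPKM. These 3 were higher in Middle and Gata2 was the one lower, with adjusted p-values over the list alone of 0.0383 for Gata4, Zfpm1 and Gata2 and 0.0402 for Ldb1 (limma). With the GC trend of each library removed Gata2 alone passed over the list (0.0378), and Gata4 and Zfpm1 (0.112 each) and Ldb1 (0.241) did not (adjusted p, limma). As a whole the list did not move apart from other genes (adjusted p = 0.233, camera). It passed the test for change in either direction (adjusted p = 0.0195, fry), which does not compare a list with the other genes.

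The second question was testosterone production. Star, which brings cholesterol into the mitochondria where steroid synthesis begins, was at 5.80 ± 1.10 RPKM in Control and 3.44 ± 0.67 in Middle (SD, n = 3 each; chromosome 8, 26296583 to 26306010), a ratio of 0.593. Each Middle library lay below each Control library, and the log2 fold change of -0.61 (SE 0.15) had an adjusted p of 0.178 over all genes and 0.0728 over the steroidogenesis list alone (limma). Cyp11a1, which cuts the cholesterol side chain, was at 3.57 ± 0.32 RPKM in Control and 2.81 ± 1.05 in Middle, and Cyp17a1, which makes androgens from progestins, at 23.2 ± 0.76 and 20.02 ± 6.71 (SD, n = 3 each). The libraries of the groups overlapped for both, and the spread of Cyp17a1 in Middle was wider than its difference between groups.

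The means of Hsd3b1, Hsd3b6, Hsd17b3 and the Leydig cell hormone Insl3 were not lower in Middle, and none of these genes passed the test. Hsd3b1 was at 11.1 ± 2.39 RPKM in Control and 12.7 ± 2.82 in Middle, Hsd3b6 at 25.3 ± 2.92 and 28.7 ± 6.25, and Hsd17b3, which makes testosterone, at 13.2 ± 0.74 and 14.3 ± 3.83 (SD, n = 3 each). Insl3 was at 213 ± 20.7 RPKM in Control and 237 ± 2.87 in Middle (SD, n = 3 each; adjusted p = 0.268, limma). Lhcgr, the receptor for luteinizing hormone, was at 0.25 ± 0.08 and 0.23 ± 0.06 RPKM (SD, n = 3 each), below the filter, and was not tested. Nr5a1, a transcription factor of steroid-producing cells, was at 3.497 ± 0.42 and 4.35 ± 0.31 RPKM, and Nr0b1, a repressor of it, at 3.61 ± 0.67 and 4.79 ± 0.09 (SD, n = 3 each). Sult1e1, an estrogen sulfotransferase of Leydig cells, was at 7.60 ± 1.86 and 4.88 ± 0.55 RPKM.

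Of 22 tested steroidogenesis genes 16 lay above 0 and 6 below, none passed over all genes or over the list alone, and the list did not move apart from other genes (adjusted p = 0.434, camera). The steroidogenesis list passed the test for change in either direction (adjusted p = 0.044, fry). Of 17 tested Leydig cell genes 12 lay above 0 and none passed either way (adjusted p = 0.532, camera). Without Middle replicate 3, the Middle library with the lowest Leydig list, that list passed as higher in Middle (median 0.30, adjusted p = 0.00308, camera; adjusted p = 0.58 with an estimated correlation). Its direction against other genes turned down without Control replicate 2, Middle replicate 1 or Middle replicate 2 (adjusted p 0.708 to 0.918, camera). The medians were then 0.039, 0.04 and 0.026, against 0.159 with every library. Without Middle replicate 1 the mean of the steroidogenesis list relative to all genes turned from 0.03 to -0.04 (adjusted p = 0.74, camera). Of 18 cholesterol synthesis genes 0 passed over all genes, and the list did not move apart from the others (adjusted p = 0.785, camera). It also passed the test for change in either direction (adjusted p = 0.044, fry).

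**Figure D2:**
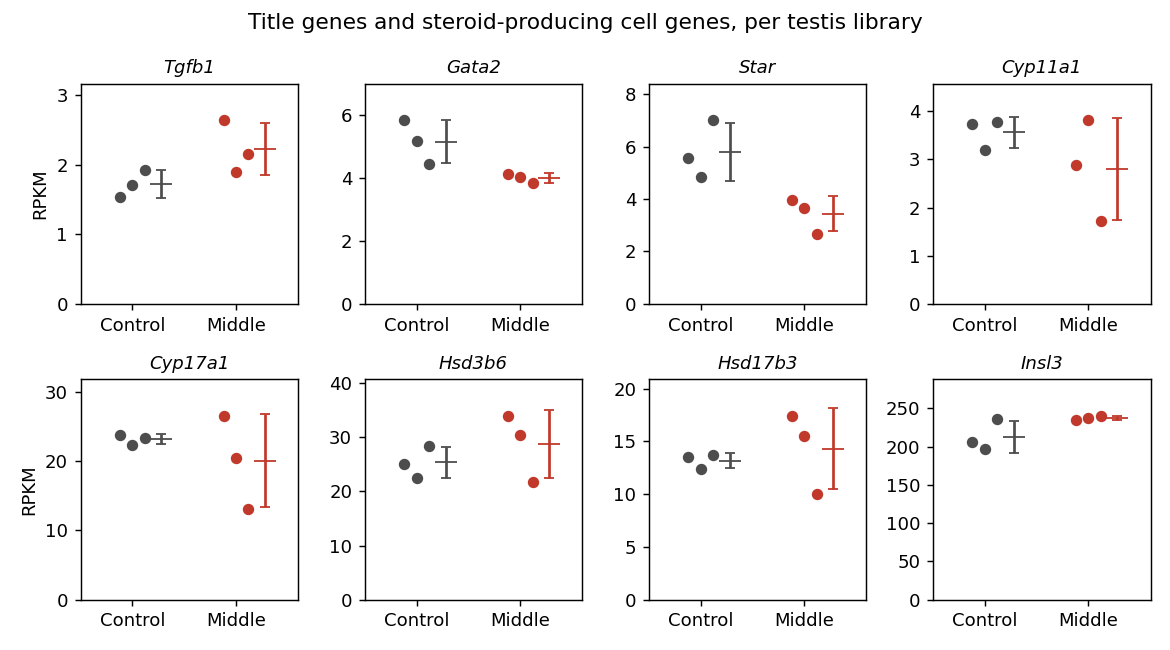
RPKM of 8 genes in each library (points; grey, Control; red, Middle), with the group mean and SD (n = 3) beside them and axes from 0. For Star and Gata2 the Middle libraries all lie below the Control libraries, and for the other 6 genes the groups overlap.

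The third question was TGF-β signalling and the mesenchymal compartment. Of 19 tested TGF-β signalling genes 14 lay above 0 in Middle and 5 below, and 0 passed over all genes or over the list alone. Smurf1, a ubiquitin ligase of the pathway, was at 14.2 ± 0.67 RPKM in Control and 16.6 ± 1.19 in Middle, and Ccn2, a matrix protein induced by TGF-β, at 5.19 ± 0.14 and 6.01 ± 0.44 (SD, n = 3 each). The receptor Tgfbr1 was at 2.19 ± 0.11 and 1.68 ± 0.27 RPKM. The list had an adjusted p of 0.179 (camera with the preset correlation) and of 0.614 with an estimated correlation. It passed the test for change in either direction (adjusted p = 0.044, fry). With the CPM filter, which let in more genes of low level (17735 tested), it passed (adjusted p = 0.0424, camera).

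Peritubular, mesenchymal and matrix genes lay above the other genes in Middle. The peritubular myoid list (median log2 fold change 0.22, 11 of 12 above 0) had an adjusted p of 0.015 (camera), the mesenchymal and stromal list (0.20, 6 of 6 tested out of 26) 0.0366, and the extracellular matrix list (0.13, 17 of 19) 0.0436. With an estimated correlation the adjusted p was 0.614 for each of these 3 lists. Tpm2, a tropomyosin of contractile cells, was at 13.5 ± 0.66 RPKM in Control and 18 ± 2.13 in Middle and was the only member of these lists to pass over its list alone, while the smooth muscle actin Actg2 was at 160 ± 13.5 and 139.6 ± 7.69 (SD, n = 3 each). Actg2 lay far above Tpm2, and the values do not tell which cells held it. The intermediate filament gene Vim was at 14.6 ± 0.49 and 18.4 ± 2.33 RPKM, and the collagen crosslinking gene Loxl1 at 2.98 ± 0.42 and 3.85 ± 0.34 (SD, n = 3 each). The mesenchymal and matrix lists did not pass without Control replicate 1, Control replicate 2, Middle replicate 1 or Middle replicate 2 (adjusted p 0.0553 to 0.306, camera), and the peritubular list not without Control replicate 2 (0.0594) or Middle replicate 2 (0.102). With the GC trend of each library removed, the mesenchymal list (adjusted p = 0.0984, median 0.16) and the matrix list (0.467, median 0.07) did not pass (camera). The rank correlation of GC content with a library's deviation from the mean of all libraries was -0.294, -0.216 and -0.246 in Control replicates 1 to 3. It was 0.446, 0.028 and -0.071 in Middle replicates 1 to 3. The groups did not overlap in it, so the GC trend cannot be told apart from the group difference. Ribosomal protein and mitochondrially encoded genes, lists fixed as signs of RNA quality, lay higher in Middle too (medians 0.24 and 0.45).

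Spermatid genes lay below the other genes in Middle. The round spermatid list had a median log2 fold change of -0.11 (20 of 26 below 0, adjusted p = 0.0009, camera) and the elongating spermatid list one of -0.11 (20 of 28 below 0, adjusted p = 0.00105, camera). With an estimated correlation the adjusted p was 0.614 for both. Over the lists alone 4 and 6 members passed, and over all genes 0. Catsper4, a subunit of the sperm calcium channel, was at 16.3 ± 1.25 RPKM in Control and 10.1 ± 1.72 in Middle, the acrosomal gene Spaca7 at 60.9 ± 5.0 and 42.9 ± 6.56, and the spermatid kinase gene Tssk1 at 54.8 ± 3.61 and 43.3 ± 0.59 (SD, n = 3 each). Among elongating spermatid genes, Capza3 was at 49.5 ± 1.83 and 40.3 ± 1.68 RPKM, Garin3 at 131 ± 13.7 and 98.5 ± 8.81, and the chaperone gene Dnajb3 at 421 ± 19.2 and 354 ± 13.9 (SD, n = 3 each). The groups did not overlap for any of these 6 genes. The genes were taken for the smallest p-values of their lists, so this adds no support. No overlap was also seen for 29.3% of all tested genes.

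Markers of Sertoli cells and spermatogonia lay on the other side. The Sertoli list (median 0.15, 23 of 26 above 0) had an adjusted p of 0.00463 and the spermatogonium list (0.20, 11 of 14) one of 0.0323 (camera), and both had 0.614 with an estimated correlation. Gstm6 of the Sertoli list was at 15.1 ± 0.84 RPKM in Control and 19.4 ± 2.35 in Middle, and of the spermatogonium list Stra8, which marks entry into meiosis, was at 8.15 ± 0.45 and 10.5 ± 1.45 and Esx1 at 4.71 ± 0.56 and 6.41 ± 0.62 (SD, n = 3 each). Of 11 tested genes of the androgen receptor and its testis targets, 10 lay above 0 (adjusted p = 0.0366, camera; adjusted p = 0.614 with an estimated correlation), and 5 passed over the list alone. Drd4, one of them, was at 0.70 ± 0.09 and 1.11 ± 0.18 RPKM (SD, n = 3 each). Early meiotic (adjusted p = 0.335) and pachytene and later spermatocyte lists (0.518) did not move apart from other genes (camera). Of the 24 tested genes of the latter, Tesmin, Piwil2, Ccna1 and Aurkc passed over the list alone, all higher in Middle (adjusted p = 0.0493 each, limma), and 0 passed over all genes. The list passed the test for change in either direction (adjusted p = 0.0461, fry). The spermatogonium list did not pass without Control replicate 2 (adjusted p = 0.0521), Middle replicate 1 (0.0835) or Middle replicate 3 (0.0594), and the androgen receptor list not without the same 3 libraries (camera). The median of the androgen receptor list was 0.22 with every library and 0.049 without Middle replicate 1. It was 0.022 with the GC trend removed as well. With the GC trend removed the androgen receptor list did not pass (adjusted p = 0.0984), and with Middle replicate 1 left out as well the Sertoli list did not (0.089, median 0.08; camera). The ribosomal protein and mitochondrially encoded lists, the signs of RNA quality, lay higher in the same comparison as these germ cell and somatic lists (medians 0.24 and 0.45).

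**Figure D3:**
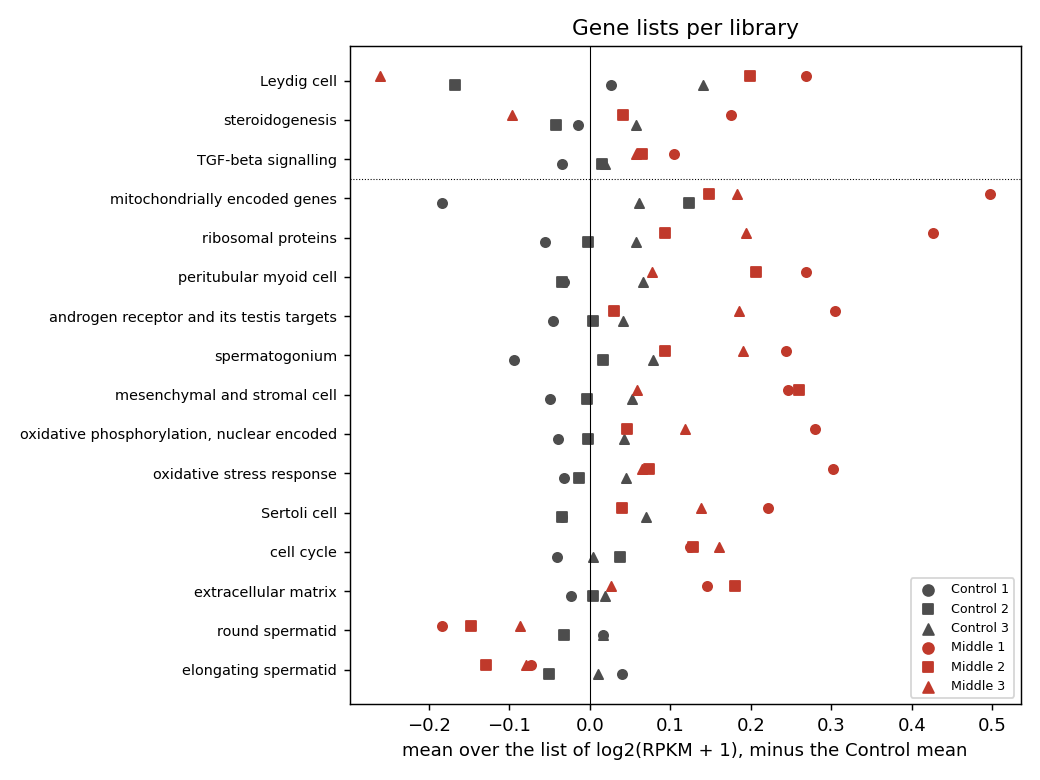
Mean over each list of log2(RPKM + 1) minus the Control mean, with 1 marker per library (grey, Control; red, Middle; circle, square and triangle for replicates 1, 2 and 3). The 13 lists past the threshold stand below the dotted line, and the TGF-β signalling, steroidogenesis and Leydig cell lists above it. Middle replicate 1 lies farthest right for mitochondrially encoded genes and ribosomal proteins, and the Middle libraries lie on both sides of 0 for the Leydig cell and steroidogenesis lists.

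Ribosomal protein genes, fixed as a sign of RNA quality, and genes of energy metabolism and division were also higher as groups in Middle. All 78 ribosomal protein genes lay above 0 (median 0.24, adjusted p = 1.16e-14, camera), as did 32 of 35 nuclear genes of oxidative phosphorylation (0.17, adjusted p = 0.000257) and 23 of 27 cell cycle genes (0.15, adjusted p = 0.0009). The oxidative stress list had 23 of 27 genes above 0 (0.16, adjusted p = 0.015). With an estimated correlation the adjusted p was 0.614 for these 4 lists, and 0 members passed over all genes. Rps3 was at 19.9 ± 0.57 RPKM in Control and 25.1 ± 2.25 in Middle, Rpl10a at 12.1 ± 2.61 and 18.6 ± 2.32, the mitotic cyclin gene Ccnb1 at 22.9 ± 1.36 and 30.5 ± 4.27, Ube2c at 4.94 ± 0.32 and 6.22 ± 0.14, and the peroxidase gene Gpx1 at 12.5 ± 0.89 and 17.1 ± 3.23 (SD, n = 3 each). Without Middle replicate 1, the library apart on component 1, the medians were 0.14 for ribosomal proteins, 0.08 for oxidative phosphorylation and 0.06 for oxidative stress, while that of the cell cycle list was 0.145 against 0.151 with it. The oxidative stress list did not pass without Middle replicate 1 (adjusted p = 0.111, camera) or without Control replicate 2.

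Mitochondrially encoded genes, also fixed as a sign of RNA quality, split in 2 directions. Reads placed on the mitochondrial genome made up 0.84% to 1.04% of reads in Control libraries and 1.18% to 1.58% in Middle. This share leaves out a copy of mitochondrial genes on chromosome 1. There Gm28437, Gm10925, Gm28661 and Gm29216 were at 2584, 3769, 3672 and 2647 RPKM in Control, while mt-Co3 was at 0.33 RPKM. These copy genes had log2 fold changes of 0.19 to 0.38 and did not pass (limma). The split of reads between the 2 places is uncertain. Of 9 tested members of the list 8 lay above 0 and mt-Nd3 below, and all 9 passed when adjusted over the list alone (list median 0.45, adjusted p = 0.00274, camera; adjusted p = 0.614 with an estimated correlation). The complex I gene mt-Nd4 was at 849 ± 97.4 RPKM in Control and 1241 ± 119 in Middle, and mt-Cytb at 873 ± 72.5 and 1104 ± 44.1 (SD, n = 3 each). mt-Nd3 (MT, 9459 to 9806), also of complex I, fell from 115.0 ± 5.01 to 51.5 ± 9.49 RPKM (SD, n = 3 each; log2 fold change -1.16, SE 0.12, adjusted p = 0.0267, limma). The only gene to rise, Gm28438 (chromosome 1, 24651856 to 24652200), an unprocessed pseudogene, went from 72.9 ± 5.4 to 127 ± 10.2 RPKM (SD, n = 3 each; log2 fold change 0.79, SE 0.08, adjusted p = 0.0267, limma). Its transcript matches mt-Nd3 at 99.71% of 345 bases, so the split of reads between the genes is uncertain. With the GC trend of each library removed, an alternative chosen after seeing the data, neither passed: the log2 fold change was -0.97 (SE 0.19) for mt-Nd3 and 0.98 (SE 0.13) for Gm28438, each with a wider SE (adjusted p 0.139 and 0.0862, limma).

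**Figure D4:**
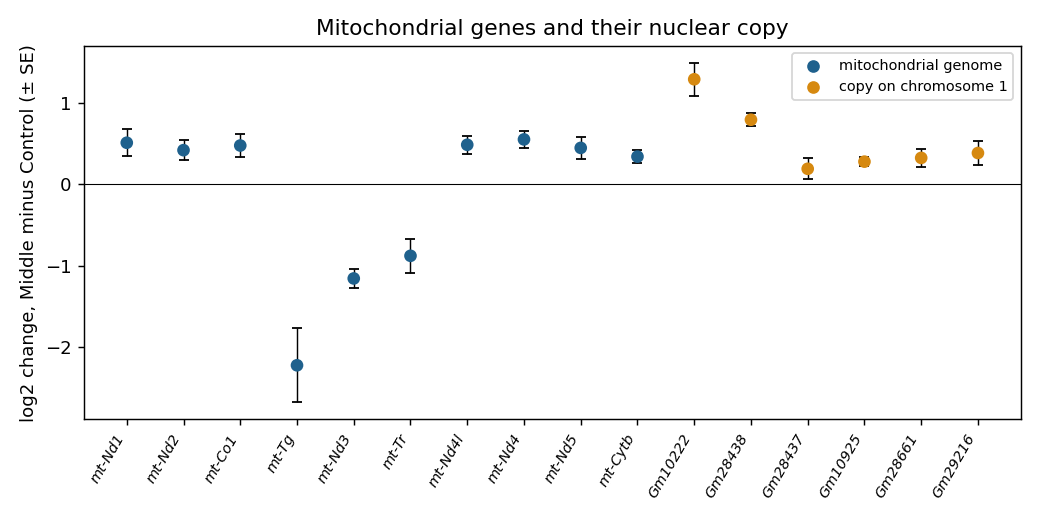
Log2 change of RPKM + 1 (Middle minus Control, points; bars, SE of the limma fit) for tested mitochondrial genes in genome order (blue) and for genes of a copy on chromosome 1 (orange). mt-Nd3 lies at -1.16 between tRNA genes that are also below 0, its copy Gm28438 lies at 0.79, and the other mitochondrial protein genes lie between 0.34 and 0.55.

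The other 6 genes that fell were non-coding or copied genes. Gm21586, a protein-coding gene in a cluster of copies (chromosome 4, 42438970 to 42439970), fell from 22.9 ± 0.91 to 12.6 ± 1.34 RPKM (SD, n = 3 each; log2 fold change -0.82, SE 0.08). The non-coding RNA genes Gm39164 (chromosome 8, 36641294 to 36643201) and Gm31518 (chromosome 8, 96320050 to 96348137) fell from 32.9 ± 0.30 to 21.1 ± 0.94 and from 6.04 ± 0.27 to 3.09 ± 0.32 RPKM (SD, n = 3 each). Gm28783 (chromosome 1, 17194971 to 17199180) fell from 2.24 ± 0.26 to 0.69 ± 0.04 RPKM, on 123 reads in Control and 37 in Middle. The microRNA genes Mir451a and Mir451b (chromosome 11, 77963996 to 77964067) lie on opposite strands of 1 place and hold the same reads, 16 in Control and 0 in Middle. With 3 fragments, or 6 reads, set as the floor over the Middle group, the fall came to 2.7-fold. The 16 Control reads were taken without their own counting error, so this is not a lower limit of the fall. The adjusted p of each of these 6 genes was 0.0267 (limma). The microRNA genes were not called with limma-voom, the CPM filter or a pseudocount of 0.01, and Gm28783 and Gm39164 not with limma-voom, nor Gm28783 with the CPM filter.

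**Figure D5:**
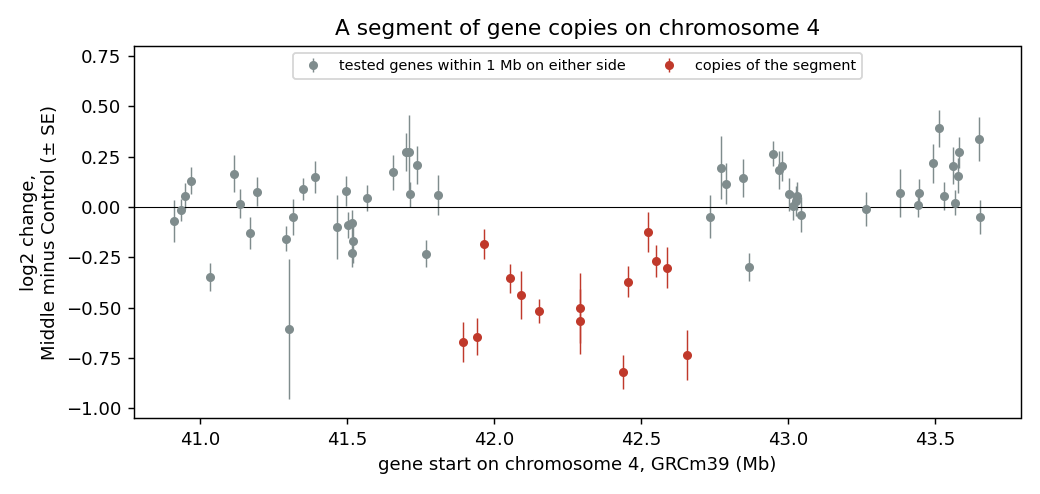
Log2 change of RPKM + 1 (Middle minus Control, points; bars, SE of the limma fit) by gene start on chromosome 4. The 14 tested genes of the segment (red) all lie below 0, with a median of -0.47, and the 54 tested genes within 1 Mb on either side (grey) have a median of 0.06.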

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

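The GC and sample weight settings, and the estimated correlation with 1 library left out, were chosen after seeing the data, and the others were fixed before. Of 8 genes called, 8 were called under median-of-ratios scaling and all 8, with 1 more, under upper-quartile scaling, and 4 of the 10 called by limma-voom (4 higher, 6 lower) were among them. The total was 0 with no filter (4204 genes at an unadjusted p under 0.05), where 38715 genes share the adjustment, 6 with the CPM filter, which tests 17735 genes (2 higher, 4 lower), 0 at an adjusted p under 0.01, 3 (0 higher, 3 lower) with a log2 fold change of at least 1 and 4 (1 higher, 3 lower) in protein-coding genes. Sample weights were 0.286, 0.667 and 2.443 for Middle replicates 1 to 3, so the Middle side rested mostly on replicate 3. They called 54 genes, 8 higher and 46 lower, among them all 8. For these settings the cause was not tested. Leaving out 1 library gave 0 to 3 genes in all, 0 higher and 0 to 3 lower. It gave 7 to 13 lists past the threshold (main 13) and 3 to 7 cell type lists (main 6), the steroidogenesis list -0.038 to 0.11 (main 0.03), Hsd3b1 -0.003 to 0.33, Hsd17b3 -0.071 to 0.30 and Cyp17a1 -0.47 to 0.009. With an estimated correlation, and with fry, 0 lists and 0 cell type lists passed, and 12 lists passed fry's test for change in either direction. With the GC trend removed 9 of 14003 tested genes were called, 1 higher and 8 lower, and 6 of them were among the 8. In that setting 10 lists passed (mesenchymal, matrix and androgen receptor lists lost), and 7 when Middle replicate 1 was left out too. The TGF-β list passed with the CPM filter (0.06, adjusted p 0.0424, camera; 0.0424 to 0.614 over its settings). Under sample weights Hsd3b1 (-0.007), Hsd3b6 (-0.073) and Hsd17b3 (-0.19) changed sign, and none of these was called. For the 54 genes carried through the settings the other values kept their direction. Counted once per gene and setting, calls of the 8 genes were lost 22 times in settings that keep every library. They were lost 45 times in those that leave 1 out. Of the genes that the naming rule takes but that were not carried through, Hbb-bs (0.127 to -0.034), H4c1 (0.079 to -0.032), Ephx1 (0.159 to -0.009) and Bpgm (0.001 to -0.041) changed sign without Middle replicate 1. Of the calls, limma-voom lost those of Gm28783 (adjusted p 0.0958) and Gm39164 (0.0649) and did not test Mir451a and Mir451b, the CPM filter left out Gm28783, Mir451a and Mir451b, and a pseudocount of 0.01 lost Mir451a and Mir451b (0.103). The call was gained by mt-Nd4 with limma-voom (adjusted p 0.0498) and by Catsper4 (0.0393) and H2-Ab1 (0.0441) under sample weights. The replicate numbers did not pair the libraries (correlations of deviations -0.153, -0.119 and 0.005), and with the replicate block 0 genes passed in all, 0 higher and 0 lower (2267 at an unadjusted p under 0.05), while 13 lists passed. The planned count tests on raw counts were not run because the table holds RPKM. With 38820385 to 58389391 reads a library and the spread between these libraries, folds of 1.25 were recovered for 8.0% of simulated genes, so changes of that size were mostly not detectable here.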

Other observations

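Tests on mt-Nd3 with its copy, on the GC trend and the read sums of chromosome 4, on depth and cell makeup of Middle replicate 1, and with an estimated correlation and 1 library left out were chosen after the result was seen. The macrophage list moved in both directions in Middle. Of 15 tested members 6 passed when adjusted over the list alone and 0 over all genes, and as a whole the list did not move apart (adjusted p = 0.401, camera). It passed the test for change in either direction (adjusted p = 0.0195, fry). The antigen presentation genes H2-Ab1 (6.80 ± 0.25 RPKM in Control, 5.03 ± 0.63 in Middle), H2-Eb1 (2.30 ± 0.40 and 1.41 ± 0.33) and Cd74 (6.06 ± 0.31 and 4.34 ± 1.12) were lower (SD, n = 3 each). Aif1, at 229 ± 23.3 and 177 ± 10.7 RPKM, was also lower, while the complement gene C1qb was at 4.62 ± 0.50 and 5.71 ± 0.24 (SD, n = 3 each). Csf1r, Cd68, Mrc1 and C1qc had log2 fold changes between -0.03 and 0.13 and did not pass. In Control they were at 1.035, 1.81, 1.86 and 2.05 RPKM, far below Aif1. The values therefore do not tell whether Aif1 transcripts came from macrophages.

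The lists of neighbouring tissues and of other cells had low medians in both groups, with single members that were not low: Wfdc10 of the epididymis list was at 19.2 RPKM in Control and 24.1 in Middle, Epcam of the rete list at 22.5 in both, Igkc of the lymphocyte list at 8.21 and 8.99 and Cidea of the fat list at 5.73 and 7.39. Median values were 0.0578 RPKM in Control and 0.0538 in Middle for epididymis genes, 0.187 and 0.185 for fat cell genes, 0.265 and 0.264 for endothelial genes, 0.168 and 0.125 for lymphocyte genes, 0.0421 and 0.0424 for mast cell and granulocyte genes and 0.108 and 0.0928 for tubal, mesothelial and rete genes. Inflammation genes had medians of 0.194 and 0.106 RPKM and interferon response genes 0.249 and 0.311. Of the remaining lists, none moved apart from other genes by camera over all 6 libraries, with adjusted p-values of 0.216 for striated muscle and for heat shock genes, 0.246 for apoptosis and p53 targets, 0.345 for red blood cells, 0.401 for histones and for the blood-testis barrier, 0.503 for signals to Leydig cells, 0.518 for endoplasmic reticulum stress, 0.69 for xenobiotic metabolism and 0.705 for immediate early genes. The endoplasmic reticulum stress list passed the test for change in either direction (adjusted p = 0.044, fry). Without Middle replicate 3 the striated muscle list passed (adjusted p = 0.0391, camera; adjusted p = 0.58 with an estimated correlation). Ciapin1 (chromosome 8, 95546432 to 95564986), chosen after its values were seen, was at 9.78 ± 0.34 RPKM in Control and 15.6 ± 1.38 in Middle (SD, n = 3 each), with an adjusted p of 0.0718 (limma) in the main test and of 0.00609 by limma-voom. It was also called among protein-coding genes only (0.0435), with the GC trend removed (0.0454) and under sample weights (0.01; adjusted p, limma). In the other settings it was not called.

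mt-Nd3 was lower in Middle while its near-identical copy on chromosome 1, Gm28438, was higher. The tRNA genes on either side did not pass the test (adjusted p = 0.178 each, limma), and mt-Tg was at 14.3 ± 3.38 RPKM in Control and 2.77 ± 2.39 in Middle, and mt-Tr at 19.5 ± 5.67 and 10.01 ± 2.15 (SD, n = 3 each). Middle replicate 1 alone is argued against, since the log2 change of its CPM was -1.32 without it. The reads of both genes summed changed by only -0.082 on the log2 scale (SE 0.10), which fits reads of 1 source being placed differently between the 2 genes, and the share of mt-Nd3 in the sum was 59.3% to 63.1% in Control and 26.9% to 31.3% in Middle, a difference of -32.5 percentage points. A candidate explanation is a difference in mitochondrial sequence between the mice of the groups, which would move reads to or from the copy; the groups are the same 2 as those of the exposure, so this cannot be told apart from a change with exposure.

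A segment of gene copies on chromosome 4 (41893278 to 42655998) was lower in Middle in all 14 tested genes, without overlap of the groups for 13. Of its genes 1, Gm21586, passed over all genes, and the ends of the segment were set from the genes that were low. The GC trend with Middle replicate 1 is argued against by a median of -0.44 with both removed. Reads moving among the copies, 10 of which match another copy at 95% or more over at least 200 bases, stay open: the summed reads of the 14 genes had a log2 change of -0.53 (SE 0.05), but this follows from the choice of the segment, and copies outside it or below the filter were not summed. A difference of this segment between the mice, such as in the number of copies, is another candidate explanation, and tested genes within 1 Mb of the ends so set had a median log2 change of 0.057. It stays open beside the exposure, because the groups carry both.

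Middle replicate 1 stood apart from the other 5 libraries. Depth is argued against, since its 47352728 reads lie inside the range of the others. The GC trend took up 16.4% of the variance of its deviation from the other Middle libraries, below the share set beforehand for a whole cause. That variance also holds counting noise and the scatter of single genes, so the share cannot decide whether GC was the whole cause. A lower share of late germ cells stays open: with the GC trend removed, its elongating spermatid list lay at -0.04 against the other Middle libraries, -0.001 (SE 0.03) against replicate 2 and -0.06 (SE 0.03) against replicate 3, and its Leydig list lay 0.12 (SE 0.08) above replicate 2 and 0.50 (SE 0.10) above replicate 3, so the outcome depends on the library it is set against. Ribosomal protein genes lay 0.26 above (SE 0.01). The SEs in this paragraph were taken over the genes of a list, which are not independent. They do not measure the spread between libraries. A biological difference of this sample was not tested.

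The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real groups gave 8 genes against at most 1 in the other splits, 7 lower against at most 1 on a side and 1 higher against at most 1. The 8 genes are not 8 separate results, since Mir451a and Mir451b hold the same reads. For the count of lists the real groups gave 13 and another split gave 15. Splits with a result as large, the real one included, numbered 1 for all genes, 2 for higher genes, 1 for lower genes and 3 for lists, so counts of lists of this size also arise between mixed groups of these libraries.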
